A study of Mus musculus with 6 samples.

How the data were processed

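Total RNA from tooth germs of wild-type and Perp-null mice at postnatal day 0 was amplified, labelled with a green dye and hybridised to Agilent mouse arrays in a single colour, per the labels' protocols. Each of the 6 samples has 1 scanner file, and the series has 1 value table with a column per sample. Samples were grouped by their titles into 3 wild-type and 3 Perp-null samples, which the labels describe as biological replicates. They do not say whether a sample pools germs of several mice.

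The scanner files hold spot intensities that Agilent Feature Extraction made, per the file headers, as a processed signal (background-subtracted and detrended), a median signal and a local background per spot. The submitters' processing notes name Feature Extraction 10.3, whereas the file headers give 10.5.1.1. The intensities were not normalised between arrays. The deposited value table holds log2 values, and no label or header says how the authors made them. Set against the scanner files, 5 columns have the rank order of median signals without background subtraction. The 6 columns are quantile normalised, since sorted columns differ by at most 0.087 from their mean. What signal the column of Perp-null replicate 2 was made from was not established. The direction and scale of the values are those of the signal and genes are not centred. Column medians were 8.37, 8.37 and 8.36 for wild-type and 8.39, 8.39 and 8.39 for Perp-null samples. There are 0 columns left unused.

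Each value table column was compared in rank order with the median signal of each scanner file over the 41174 data probes, and a Spearman correlation of at least 0.9999 was taken as a match. By this rule 5 columns matched a scanner file, with 0 order breaks over 0.02 log2, and 1 of them matched the file of its own sample. The column of wild-type replicate 2 matched the file stored for wild-type replicate 3, that of wild-type replicate 3 the file for Perp-null replicate 1, that of Perp-null replicate 1 the file for wild-type replicate 2, and that of Perp-null replicate 3 the file for Perp-null replicate 2. The column of Perp-null replicate 2 matched none (best correlation 0.980), and the file stored for Perp-null replicate 3 matched no column. Perp, the gene removed in the mutant, went against the labels of 3 of the 6 scanner files and with those of all 6 value table columns. The design fixed before the data were examined used the scanner files, as log2 processed signal minus the 75th percentile of each array. The value table was taken as the main source instead, a change made after the data were seen, and the fit as designed is given as an alternative. No sample changed its group. Matched arrays were used only for background, slides and added alternatives. As stored, each slide of 3 arrays holds 1 genotype, so a slide block on the scanner files as stored could not be fitted.

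Probe annotation in the files gives accessions, not symbols. Accessions without versions were looked up among the RefSeq transcripts of a mouse gene table (assembly GRCm38), which named 24844 probes, against 26382 probes with a RefSeq-style accession, by 17178 symbols. The arrays' grid follows mm9, so no coordinates are given. Control spots were left out. Probes well above background, per the files' own flag, on at least 3 of the 6 arrays were kept (33736), without use of the sample labels. These arrays include the 1 that matches no column. A gene well above background only on the 3 matched wild-type arrays could pass, but one only on the 2 matched Perp-null arrays could not. With no matched wild-type array well above background, a gene such as Pou3f1 or Sox2 passed only with the array that matches no column. A gene was represented by its probe with the highest mean, chosen without regard to genotype, and unnamed probes were kept by themselves, which gave 26677 features, of which 15582 were named genes and 11095 unnamed probes. The value table carries no flags, so outlier spots were left out only in fits on scanner files. Flagged outliers numbered between 4 and 68 per array and saturated spots 0. A gene not well above background on any matched array of a group is given as "at least" a fold, from the mean of the brighter group and, for each dimmer array, the higher of the gene's value and the lowest value of a probe well above background. The array of Perp-null replicate 2 is unknown, so the flags rest on 2 Perp-null arrays. The column of Perp-null replicate 2 enters at its own value, without that lower limit.

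Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the log2 values, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors are SDs between samples or SEs of the fit. The 19 gene lists, fixed before the data were examined, cover desmosomes; adherens, tight and gap junctions; hemidesmosomes and basement membrane; epithelial keratins; cornified epithelium; enamel and ameloblasts; dental epithelium and signalling centres; dental mesenchyme; odontoblasts and dentin; p53 targets; cell cycle; immediate-early and stress genes; inflammation and interferon. Lists of skeletal muscle, red blood cells, leukocytes and osteoclasts, endothelium, nerve and glia, and cartilage stand for other tissues. Lists were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation, and with fry. The genes named in the text follow a rule set in advance. It takes Perp, the 14 named genes per direction with the largest difference among those called with non-overlapping groups, 16 fixed genes of enamel and desmosomes, and from each list up to 6 called members of the largest difference or, with none called, 4 members of the lowest p. Of the fixed genes Amtn, Dsp and Dsc3 had no tested probe. Some genes that the rule takes are not reported here.

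The fit was tested on simulated data with the means and spreads of the 26677 features and 200 changed ones. It recovered 15% of log2 changes of 1 and 60% of log2 changes of 2, and called 2 unchanged features. Among the 13525 features with a mean log2 of at least 9 the shares were 19.2% and 70.2%. The simulated noise was independent between features, with no effect shared within an array. These shares and the 2 false calls therefore need not hold for the measured data.

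Alternatives set in advance were the scanner files as stored with 75th percentile scaling, with normexp (offset 50) or with quantile normalisation, no filter on dim probes, probes well above background on all 6 arrays, every probe by itself, the replicate number as a block, an intensity trend with robust fit, array weights, leaving out each sample in turn, and camera with an estimated correlation. Normexp was planned on the mean signal and used the median signal, since the files hold no mean signal. Alternatives added after the data were seen were the 5 matched scanner arrays with 75th percentile scaling or with normexp and quantile normalisation, the slide as a block on the 5 matched columns, genes of mean log2 of at least 9, and these with the replicate block.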

Results

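The series measured messenger RNA in tooth germs of mandibular molars taken from newborn mice (postnatal day 0) that carry or lack Perp. Perp encodes a membrane protein of desmosomes, the junctions that hold epithelial cells together, and its transcription is activated by p53. The comparison asks which genes differ in a developing tooth without Perp, and the lists set against it cover desmosomes, other junctions, enamel formation, the dental mesenchyme and the other tissues a dissected germ can hold. There were 3 wild-type and 3 Perp-null samples, described as biological replicates, all from male mice of the same inbred strain. Each sample was hybridised to 1 array in a single colour, so the number of arrays limits the precision. Values are log2 intensities from the deposited value table, in which the median of each of the 6 columns lay between 8.36 and 8.39. A gene is called higher or lower here when its Benjamini-Hochberg adjusted p in limma was under 0.05, and all differences are Perp-null minus wild-type.

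Perp was far lower in the Perp-null columns of the value table. Its log2 level was 16.98 ± 0.03 (SD, n = 3) in wild-type germs and 7.67 ± 0.51 (SD, n = 3) in Perp-null germs, a difference of -9.31 (SE 0.26, limma adjusted p = 0.000114), or 635-fold on the scale of the value table, which is not background-subtracted. The wild-type columns read 17.01, 16.95 and 16.98, and the Perp-null columns read 7.51, 8.24 and 7.26, each below the median of its column. The scanner files gave another picture under the samples they are stored for. Perp had a processed signal of 126047.2 and 132515.3 in the files stored for wild-type replicates 1 and 3 but 50.6 in the file stored for wild-type replicate 2, and 114351.6, 17.0 and 138248.8 in the files stored for Perp-null replicates 1, 2 and 3. In rank order over 41174 probes, 5 columns equalled a scanner file, and only 1 of these, wild-type replicate 1, equalled the file stored for its own sample. With the scanner files taken as stored and scaled to the 75th percentile, the Perp difference was -0.59 (limma adjusted p = 1.00). On the 5 matched arrays, with background-subtracted signal scaled the same way, it was -11.85 (limma adjusted p = 0.0461). All further comparisons rest on the value table. Through the matched arrays, slide 1 held wild-type replicates 1 and 2 with Perp-null replicate 1 and slide 2 held wild-type replicate 3 with Perp-null replicate 3. The Perp difference was -9.47 within slide 1, -9.72 within slide 2 and -9.58 with slide as a block (limma adjusted p = 0.00350). With the replicate number as a block it stayed at -9.31, and its adjusted p was 0.0799 with 2 residual degrees of freedom.

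**Figure D1:**
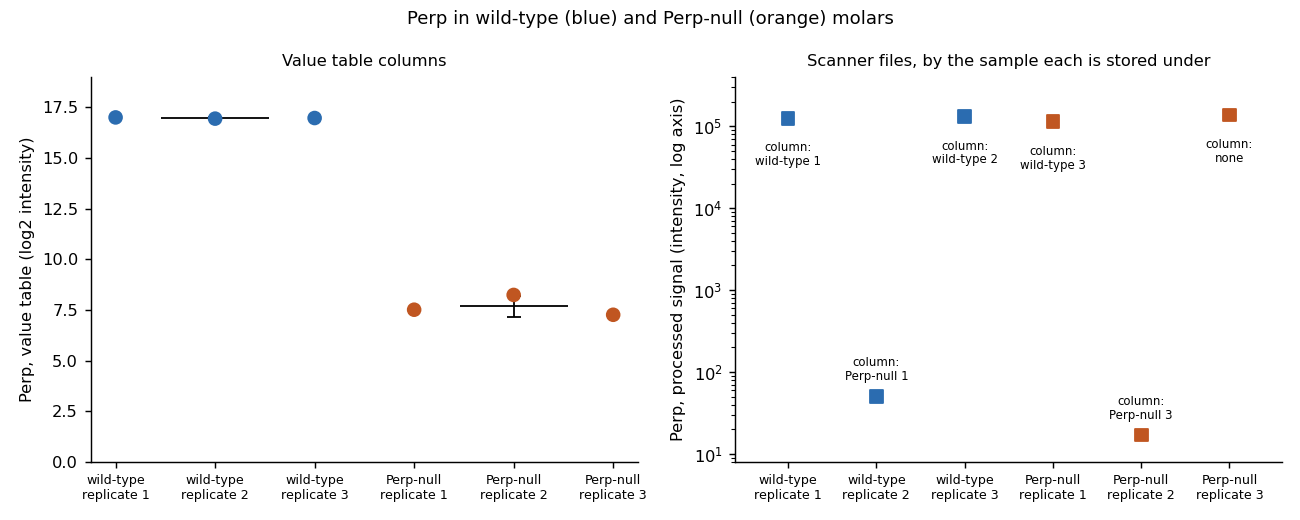
Perp in each of the 6 value table columns (left, log2 intensity, with the mean and SD of each genotype in black) and in each of the 6 scanner files (right, processed signal on a log axis), coloured by the genotype of the sample each is stored under. The value table separates the genotypes (17.01, 16.95 and 16.98 against 7.51, 8.24 and 7.26), whereas the scanner files stored for wild-type replicate 2 and for Perp-null replicates 1 and 3 have the Perp signal of the other genotype; text beside each square names the column with the same rank order.

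Apart from Perp, the genes called between genotypes were mostly dim. Of 26677 genes and unnamed probes tested, 2413 were higher and 3635 lower in Perp-null germs, and among named genes 665 were higher and 1662 lower. The filter could admit a gene through the 3 matched wild-type arrays alone but not through the 2 matched Perp-null arrays alone. This can favour genes lower. The mean log2 level was under 9 for 5641 of the 6048 calls, or 93.3%. At mean levels from 12 to 14, 1 of 4096 genes was called higher and 3 lower, Perp among them, and none of 2035 genes at 14 or above was called. The groups did not overlap for 43.2% of genes, where chance gives 10%. The signal of negative control spots, which carry no mouse sequence, differed between genotypes on the matched arrays: its median was 80 to 127 on the 3 matched wild-type arrays and 32 to 37.5 on the 2 matched Perp-null arrays. Both matched Perp-null arrays lay at position 2 of their slide, and the matched wild-type arrays at positions 1 and 3. Position therefore cannot be told apart from genotype on these arrays, and a slide block does not remove it. The smallest adjusted p after that of Perp was 0.0258.

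The counts depended on the setting. With the replicate number as a block, limma called 0 genes higher and 0 lower (10144 at an unadjusted p under 0.05), with 2 residual degrees of freedom, so none of the genes named below is called in that fit. Without wild-type replicate 1, Perp-null replicate 2 or Perp-null replicate 3, limma called 0 genes higher and 1, Perp, lower (8985, 8022 and 7806 genes at an unadjusted p under 0.05), and without wild-type replicate 3 it called 1212 higher and 1975 lower. Without wild-type replicate 2 it called 2049 higher and 3109 lower, and without Perp-null replicate 1 it called 2072 higher and 2967 lower. In the first 3 of these fits, which share 5 samples with the main one, the smallest adjusted p after Perp was 0.0541, 0.0857 and 0.0823, and log2 differences correlated across genes with the main ones at 0.985, 0.987 and 0.982. With probes well above background on all 6 arrays, limma called 695 higher and 676 lower. On the 5 matched arrays, background-subtracted and scaled to the 75th percentile, it called 36 higher and 6947 lower, or 0.5% of calls higher against 39.9% in the main fit, and shared 15 of the 2413 genes higher and 2822 of the 3635 lower. With the slide as a block on the 5 matched columns, or with only the 13525 genes of mean log2 of at least 9, limma again called 0 higher and only Perp lower (8478 and 1274 at an unadjusted p under 0.05), and with the scanner files as stored it called 0 in either direction (869 at an unadjusted p under 0.05).

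**Figure D2:**
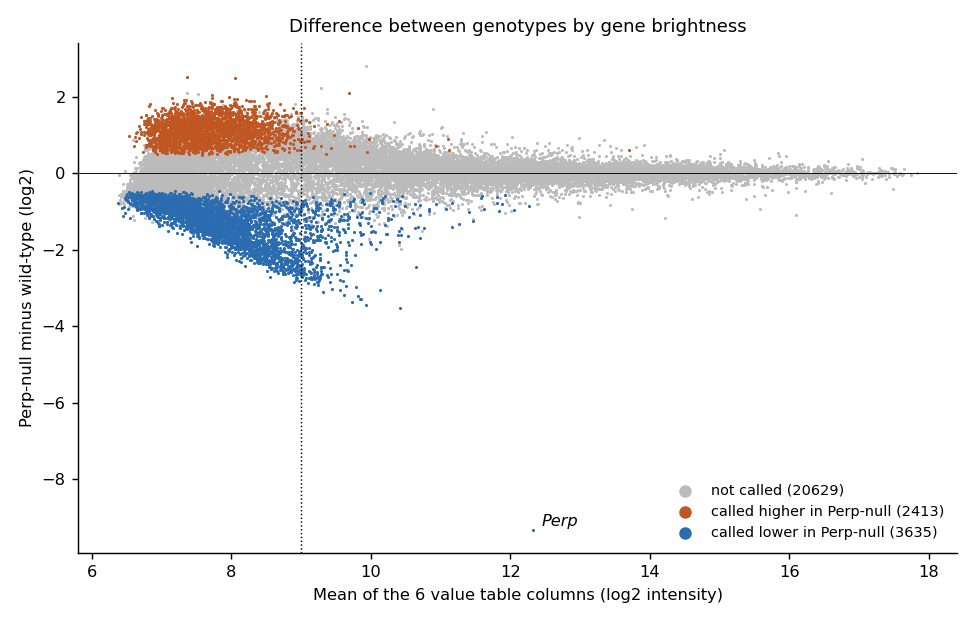
Difference between genotypes (log2, Perp-null minus wild-type) against the mean level of the 6 columns (log2 intensity) for 26677 genes and unnamed probes, coloured by limma call; the dotted line marks a mean log2 of 9. Perp, at -9.31, stands apart, and 93.3% of the calls lie left of the line.

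The named genes with the largest increases had mean log2 levels between 7.35 and 9.69. All of them but Klk1b24 and Cyp2g1 read lowest in wild-type replicate 3. The array of that sample had the highest negative control median of the matched arrays, 127. Without quantile normalisation, 22% of all 2413 genes called higher were higher on the matched arrays, in median signal scaled to the 75th percentile. A rise in expression therefore cannot be told apart from a difference between arrays or from quantile normalisation for these genes. Chil3, a chitinase-like protein secreted by macrophages, rose from 6.81 ± 0.69 to 9.30 ± 0.51 (SD, n = 3 each), a log2 difference of 2.49 (SE 0.40, adjusted p = 0.0258) or 5.62-fold. Klk1b24, a glandular kallikrein, rose by 2.10 (SE 0.50, adjusted p = 0.0305) and Cyp2g1, a cytochrome P450 of the olfactory mucosa, by 1.92 (SE 0.49, adjusted p = 0.0359). Another Cyp2g1 probe read -0.55 (adjusted p = 0.145). Pou3f1, a POU-domain transcription factor, was not well above background on any of the 3 matched wild-type arrays and was at least 3.44-fold higher in Perp-null germs (adjusted p = 0.0258). It was well above background on the array that matches no column, in which Perp was bright. The transcription factor Ebf2 rose by 1.83, Klhl4 by 1.81, Tbc1d24 by 1.74 and the formyl peptide receptor Fpr2 by 1.72. The phosphatase Cdc25a, which drives entry into S phase, and the neuronal protease inhibitor Serpini1 both rose by 1.71. The oviduct glycoprotein Ovgp1 rose by 1.69, the melanocortin receptor Mc4r by 1.68, the splicing factor Srrm1 by 1.67 and Gtse1, a G2 and S phase protein induced by p53, by 1.64.

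The largest decreases after Perp were in genes of mean log2 levels between 8.92 and 9.92. Each gene named here read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. Among matched arrays, theirs had the highest and lowest negative control medians, 127 and 32. Loss of expression therefore cannot be told apart from a difference between arrays, in background or otherwise, for these genes. Each was well above background on the 3 matched wild-type arrays, whose columns had a 75th percentile of 10.98. Whether background of the size seen in the negative controls could give such differences was not settled. Ffar2, a receptor for short-chain fatty acids, fell from 11.64 ± 0.99 to 8.21 ± 0.91 (SD, n = 3 each), a log2 difference of -3.44 (SE 0.60, adjusted p = 0.0258) or 10.8-fold. It read 11.24, 10.92 and 12.77 in wild-type replicates 1, 2 and 3, and 9.18, 8.06 and 7.38 in Perp-null replicates 1, 2 and 3. The neural homeobox gene Barhl2 fell by 3.29 (SE 0.58, adjusted p = 0.0258) on its brighter probe and had -0.60 on the other, and Thrsp, a thyroid hormone-responsive gene of lipid synthesis, fell by 3.20 (SE 0.57, adjusted p = 0.0258). The axonal adhesion gene Nfasc had -2.98 on its brightest probe and 0.52 on another (adjusted p = 0.0540). The microtubule-associated gene Map1a had -2.85 on its brightest probe. Its other probes read -1.69 (adjusted p = 0.0243), -1.62 (adjusted p = 0.0269) and 1.20 (adjusted p = 0.0243). The chromatin remodeller Chd5 had -2.79 on its brightest probe and -0.033 on another (adjusted p = 0.911). The remaining genes fell with log2 differences of -2.94 for the heart homeobox gene Irx4, -2.92 for the neutrophil chemokine receptor Cxcr2, -2.82 for the neuronal RNA-binding gene Celf3, -2.79 for Etv2, a factor of early blood vessels, -2.78 for the posterior homeobox gene Hoxc10, -2.78 for the potassium channel Kcnj9 and -2.77 for Trim50. Over all 5509 genes with several tested probes, 86 had one probe called higher and another called lower.

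No shift of the desmosome genes as a group was detected. Of 14 measured members, 1 rose, 1 fell and 12 were not called, and adjusted over the list alone 0 rose and 1 fell. The desmocollin Dsc1 fell by 1.77 (SE 0.34, adjusted p = 0.0258), from 9.15 ± 0.68 to 7.38 ± 0.23 (SD, n = 3 each), and the desmoglein Dsg3 rose by 0.71 (SE 0.19, adjusted p = 0.0398), both with a mean log2 under 9. Dsg3 read -0.83 instead on the 5 matched scanner arrays scaled to the 75th percentile. Like the largest decreases, Dsc1 read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. Its fall therefore cannot be told apart from a difference between arrays. Brighter members were not called. The plakophilins Pkp1 and Pkp3 differed by 0.047 (adjusted p = 0.906) and 0.13 (adjusted p = 0.729), Dsg2 by 0.19 (adjusted p = 0.510), Dsc2 by 0.18 (adjusted p = 0.596) and plakoglobin, Jup, by -0.20 (adjusted p = 0.448). The list's median log2 difference was 0.062 and its mean -0.066, and camera gave an adjusted p of 0.916 (0.965 with an estimated correlation). In limma's fry the list's p was 0.853 (0.913 adjusted over the 19 lists) for a change in one direction and 0.0570 (0.120 adjusted) for change in either. When a single sample was left out the median lay between -0.0050 and 0.097. It was 0.0075 within slide 1, 0.13 within slide 2 and 0.095 with slide as a block. Dsp and Dsc3 had no tested probe.

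Among 28 measured genes of adherens, tight and gap junctions, 0 rose and 3 fell, and adjusted over the list alone 2 fell. These were claudins of tight junctions: Cldn4 at -1.60 (SE 0.31, adjusted p = 0.0258), Cldn3 at -1.32 (SE 0.27, adjusted p = 0.0258) and Cldn16 at -0.54 (SE 0.15, adjusted p = 0.0461), and 2 of the 3 had a mean log2 under 9. Cldn3 and Cldn4 read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. The limit given for the largest decreases therefore holds for them too. None of the 23 hemidesmosome and basement membrane genes was called, over all genes or adjusted over the list alone, with Lama2 at -0.46 (adjusted p = 0.172), Plec at -0.38 (adjusted p = 0.280) and Fermt1 at 0.39 (adjusted p = 0.449). Camera gave an adjusted p of 0.916 for both lists. The hemidesmosome median was -0.050, but 0.079 on the 5 matched arrays scaled to the 75th percentile, where the list passed upward (camera adjusted p = 0.0106). The junction list had a median of 0.048 and a mean of -0.10, and its median lay between -0.029 and 0.0575 when a single sample was left out.

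No enamel or ameloblast gene passed the test, over all genes or adjusted over the list alone, among 22 measured members. Amelogenin, Amelx, read 17.69 ± 0.16 in wild-type and 17.28 ± 0.61 in Perp-null germs (SD, n = 3 each), a difference of -0.41 (adjusted p = 0.414). Ameloblastin, Ambn, differed by -0.93 (SE 0.75, adjusted p = 0.451) and enamelin, Enam, by -1.18 (SE 0.81, adjusted p = 0.361), with SDs of 0.59 and 0.57 among wild-type and 1.58 and 1.72 among Perp-null germs. The enamel proteases Mmp20 and Klk4 differed by -0.81 (adjusted p = 0.617) and -0.97 (adjusted p = 0.437), with SDs of 1.16 and 1.18 among wild-type and 1.74 and 1.22 among Perp-null germs, Odam by 0.26 (adjusted p = 0.374), Tuft1 by 0.11 (adjusted p = 0.772), Wdr72 by 0.60 (adjusted p = 0.0760) and Lamb3 by -0.55 (adjusted p = 0.408). The list's median was -0.097 and its mean -0.24, with a camera adjusted p of 0.916 (0.965 with an estimated correlation). The fry p was 0.762 (0.913 adjusted) for a change in one direction and 0.514 (0.610 adjusted) for change in either. The sign of the median depended on single samples, as it was 0.046 without wild-type replicate 1, 0.038 without Perp-null replicate 2 and -0.265 without Perp-null replicate 1. It was 0.22 within slide 1, -0.13 within slide 2 and 0.081 with slide as a block (camera adjusted p = 0.583). On the 5 matched scanner arrays scaled to the 75th percentile the median was 0.15 and the list passed upward (camera adjusted p = 0.0106), while the median of all genes there was -0.30. With the replicate number as a block on the genes of mean log2 of at least 9 the median was -0.13 and the list passed downward (14 of 19 members lower, camera adjusted p = 0.0122, 0.768 with an estimated correlation). Between samples of the same number, 8 of the 22 genes were lower in all 3 numbers and 3 were higher, against 33.3% and 33.4% of all tested genes. Klk4 differed by -0.91, -0.83 and -1.16 (adjusted p = 0.0858 with the replicate block), Mmp20 by -0.19, -1.36 and -0.89 (0.112) and Lamb3 by -0.29, -0.80 and -0.55 (0.0901), genes singled out after their values were seen. Amtn had no tested probe.

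The other tooth lists held few calls. Among 36 genes of the dental epithelium and its signalling centres, 2 rose and 1 fell, the same numbers as adjusted over the list alone. Fgf20, a growth factor of signalling centres, fell by 2.46 (SE 0.47, adjusted p = 0.0258), Axin2, a target of Wnt signalling, rose by 1.53 (SE 0.34, adjusted p = 0.0271). The stem cell factor Sox2, not well above background on any matched wild-type array, was at least 1.99-fold higher (adjusted p = 0.0258), but read -0.094 on the 5 matched arrays scaled to the 75th percentile. Sox2, too, was well above background on the array that matches no column, in which Perp was bright. Fgf20, Axin2 and Sox2 all had a mean log2 under 9. Of 25 dental mesenchyme genes 2 fell, Dlx6 at -1.19 (adjusted p = 0.0382) and Sall1 at -0.91 (adjusted p = 0.0308), and 0 did so adjusted over the list alone. Fgf20, Dlx6 and Sall1 read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. The limit given for the largest decreases therefore holds for them too. None of 22 odontoblast and dentin genes was called, over all genes or adjusted over the list alone, with Dmp1, a dentin matrix protein, at -0.76 (adjusted p = 0.508), Mepe at 0.65 (adjusted p = 0.290), Dkk1 at 0.45 (adjusted p = 0.582) and Ank at -0.16 (adjusted p = 0.543). The camera adjusted p was 0.344 for the dental epithelium, 0.778 for the dental mesenchyme and 0.916 for the odontoblast list, whose median was -0.053 and mean 0.026, and whose median lay between -0.32 and 0.20 when a single sample was left out.

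Genes of cornified oral or skin epithelium went both ways, with 3 of 23 higher and 4 lower, or 5 and 5 adjusted over the list alone. Those lower included the keratin Krt2 at -2.28 (SE 0.46, adjusted p = 0.0258) on its brighter probe, the envelope protein involucrin, Ivl, at -1.89 (SE 0.36, adjusted p = 0.0258) and Sprr1b at -1.36 (adjusted p = 0.0271). Sprr1a rose by 1.25 (adjusted p = 0.0290), loricrin, Lor, by 0.89 (adjusted p = 0.0301) and the transglutaminase Tgm3 by 0.67 (adjusted p = 0.0362). Of these 7 calls 6 had a mean log2 under 9, and on the 5 matched arrays scaled to the 75th percentile Sprr1a read -0.51 and Tgm3 -1.63. Among 16 epithelial keratins, 1 fell, over all genes and adjusted over the list alone: Krt4, a keratin of the oral mucosa, at -1.61 (SE 0.29, adjusted p = 0.0258). Krt2, Ivl, Sprr1b and Krt4 read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. The limit given for the largest decreases therefore holds for them too. The camera adjusted p was 0.922 for the cornified list and 0.904 for the keratins.

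Of 28 targets of p53, 2 rose, or 1 adjusted over the list alone: Gtse1, above, and the pro-apoptotic gene Pmaip1, by 1.21 (SE 0.22, adjusted p = 0.0258), which read -0.42 on the 5 matched arrays scaled to the 75th percentile. None of 38 cell cycle genes was called, over all genes or adjusted over the list alone, with E2f1 at 0.64 (adjusted p = 0.250), Aurkb at 0.65 (adjusted p = 0.466), Ccna2 at 0.37 (adjusted p = 0.661) and Mcm7 at 0.32 (adjusted p = 0.644). The cell cycle median of 0.15 depended on single samples. It was -0.24 without wild-type replicate 1, -0.10 without Perp-null replicate 2 and -0.023 without Perp-null replicate 3, and 0.57 without Perp-null replicate 1, where the list passed (camera adjusted p = 0.00126). It also passed with array weights (0.50, adjusted p = 0.0209) and with the replicate block on genes of mean log2 of at least 9 (33 of 38 higher, adjusted p = 0.0122, 0.768 with an estimated correlation). Of 29 immediate-early and stress genes 2 rose, and 0 adjusted over the list alone: Egr2 by 0.89 (adjusted p = 0.0354) and Fosb by 0.78 (adjusted p = 0.0417), which read -0.27 and -1.66 on the 5 matched arrays scaled to the 75th percentile. Among 25 inflammation and interferon genes 1 rose and 4 fell, the same numbers as adjusted over the list alone. The genes that fell were the interferon-induced gene Ifi44 at -1.69 (SE 0.34, adjusted p = 0.0258), the chemokine Ccl7 at -1.31 (adjusted p = 0.0307) with another probe not called (adjusted p = 1), the interferon factor Irf7 at -1.10 (adjusted p = 0.0265) and the interleukin antagonist Il1rn at -0.87 (adjusted p = 0.0294). Lcn2 rose by 1.20 (adjusted p = 0.0260) but read -0.60 on the 5 matched arrays scaled to the 75th percentile. Ifi44, Ccl7, Irf7 and Il1rn read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. The limit given for the largest decreases therefore holds for them too. The camera adjusted p was 0.601 for the p53 and the cell cycle lists, 0.375 for the stress list and 0.904 for the inflammation list.

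Markers of other tissues that a dissected germ can carry also differed in single genes. Skeletal muscle held the most calls of any list, with 7 of 23 members lower and 2 higher, or 8 and 3 adjusted over the list alone. The largest decreases were -2.62 for Mybph (SE 0.51, adjusted p = 0.0258), -2.41 for the troponin Tnnc1 (SE 0.47, adjusted p = 0.0258), -2.04 for nebulin, Neb, on its brightest probe, -1.66 for desmin, Des, -1.63 for the myosin Myh1 and -1.61 for Tcap, and 5 of the 9 calls had a mean log2 under 9. The muscle list's median was -0.38 (camera adjusted p = 0.344, 0.965 with an estimated correlation), -0.43 within slide 1, -1.42 within slide 2 and -0.91 with slide as a block, where it passed (camera adjusted p = 0.0108). The slide block also leaves out Perp-null replicate 2, and without that sample and with no block the median was -0.83 and the list passed (camera adjusted p = 0.0173). Without Perp-null replicate 1 it was -0.14, without Perp-null replicate 3 -0.15 and without wild-type replicate 3 -0.21. Among 18 nerve and glia genes 1 rose and 5 fell, the same numbers as adjusted over the list alone. Those that fell included the neuronal filament gene Prph at -1.76 (SE 0.31, adjusted p = 0.0258), the growth cone gene Gap43 at -1.19 and the receptor Erbb3 at -1.32 on its brightest probe. Other Erbb3 probes read -1.17 (adjusted p = 0.0281), -0.72 (adjusted p = 0.101) and 0.38 (adjusted p = 0.145). Cdh19 was not well above background on either matched Perp-null array. It was 1.53-fold lower with the lower limit set on these arrays only, so this is not a strict bound. All 6 called members had a mean log2 under 9. Of 15 cartilage genes 2 fell, or 1 adjusted over the list alone, the collagen Col9a1 at -1.74 and the matrilin Matn1 at -1.49. The muscle, nerve and cartilage genes named here as lower all read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. The limit given for the largest decreases therefore holds for them too.

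Of 15 red blood cell genes 1 rose, over all genes and adjusted over the list alone, the embryonic globin Hbb-y by 1.53 (adjusted p = 0.0274). Of 29 genes of leukocytes and osteoclasts 2 rose and 1 fell, and 0 did so adjusted over the list alone. Cd163 rose by 1.11 and Cd3e by 0.68, which read -0.86 and -1.40 on the 5 matched arrays scaled to the 75th percentile, and Cd52 had -1.11 as the member that fell. Of 19 endothelial genes 1 fell, and 0 adjusted over the list alone: the adhesion gene Esam at -1.24 (adjusted p = 0.0385), while the list's median was 0.41, or -0.095 without wild-type replicate 3. Cd52 and Esam, too, read highest in wild-type replicate 3 and lowest in Perp-null replicate 3. The camera adjusted p was 0.344 for nerve and glia, cartilage and red blood cells, and 0.601 for leukocytes and endothelium. Over all 19 lists camera passed 0 at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05, with a preset or an estimated correlation. The smallest adjusted p was 0.344 with the preset and 0.965 with the estimated correlation. In other settings more lists passed in camera. With the replicate block on genes of mean log2 of at least 9 these were, besides enamel and cell cycle, cartilage (7 of 8 lower, adjusted p = 0.0122) and skeletal muscle (11 of 14 lower, adjusted p = 0.0241), each at 0.768 with an estimated correlation. With the 5 matched arrays scaled to the 75th percentile 10 lists passed. Besides enamel and hemidesmosomes these were dental epithelium, dental mesenchyme, p53 targets, cell cycle, stress genes and endothelium upward, and inflammation and skeletal muscle downward (adjusted p between 0.0106 and 0.0461). Upward is relative to other genes here: the median of all genes was -0.30, and that of the cell cycle list -0.061. Red blood cells passed upward without wild-type replicate 2 (0.92, adjusted p = 0.0285). Skeletal muscle passed downward with probes well above background on all 6 arrays (-0.68, adjusted p = 0.00306) and with only genes of mean log2 of at least 9 (-0.31, adjusted p = 0.00102).

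Fry asks whether members differ, without comparing them with other genes. For a change in one direction its smallest p was 0.0214 for the dental epithelium and 0.0344 for nerve and glia (both 0.327 adjusted). For change in either direction it gave 0.00144 for cornified epithelium (0.0274 adjusted), and 0.00419 for inflammation, 0.00673 for nerve and glia, 0.00739 for junctions, 0.00948 for keratins and 0.0108 for skeletal muscle (each 0.0343 adjusted). Cartilage had 0.0488 (0.120 adjusted). In limma 9766 of all 26677 tested features had an unadjusted p under 0.05, so a pass in fry does not set a list apart from other genes.

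**Figure D3:**
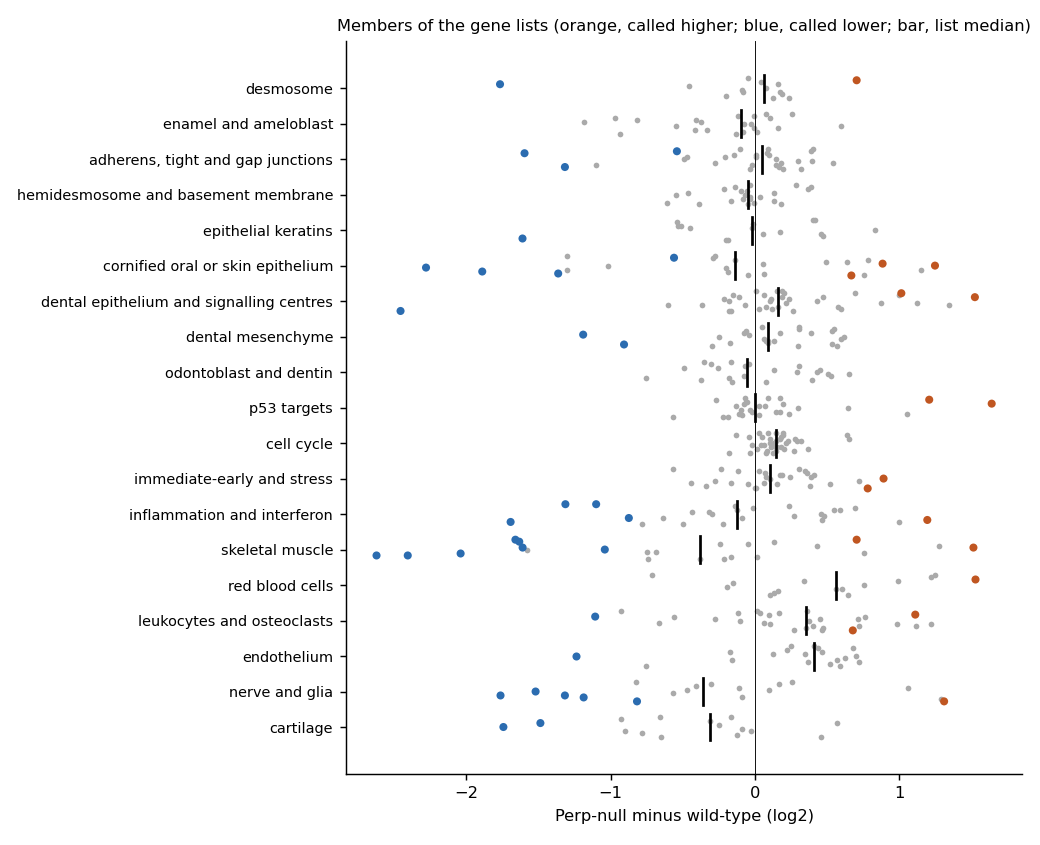
Difference between genotypes (log2, Perp-null minus wild-type) of each measured member of the 19 gene lists; orange and blue points are members called higher and lower by limma, grey points were not called and black bars are list medians. Skeletal muscle has 7 members lower and 2 higher, and the enamel, odontoblast, cell cycle and hemidesmosome lists have no called member.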

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

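Perp was bright in a scanner file whose signals the comparisons on the value table do not use. The scanner file stored for Perp-null replicate 3 has the rank order of no value table column, and its processed signal for Perp was 138248.8, above the 126047.2 and 132515.3 of the files stored for wild-type replicates 1 and 3. The value table column of the same sample reads 7.26 for Perp on the log2 scale. Whether this array belongs to the study's samples was not settled. Its signals enter only the fits of the scanner files as stored, but its flags enter the filter on probes well above background in other fits too. The disagreement between scanner files and columns is weighed under the other observations.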

How the results depend on the processing

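Tests on matched arrays, with slide as a block and on brighter genes were chosen after the results were seen, and the other settings before. Perp kept its sign in all 20 alternatives, between -11.85 and -0.12, and its call in 16. It was not called with the scanner files as stored, at -0.59 with 75th percentile scaling, -0.12 with normexp and -0.18 with quantile normalisation, where 3 files carry the Perp signal of the other genotype. Leaving out a sample gave -9.59 to -9.11. The main counts were 2413 higher and 3635 lower. They were 0 and 0 in each of the 3 scanner settings as stored (869, 363 and 420 genes at an unadjusted p under 0.05), 2974 and 3697 without a filter on dim probes, 695 and 676 with probes well above background on all 6 arrays, 3382 and 4261 with every probe by itself, 2318 and 3934 with an intensity trend and robust fit, and 3096 and 4421 with array weights. Leaving out a sample gave 0 to 2072 higher and 1 to 3109 lower. Without wild-type replicate 3 they were 1212 and 1975, and without wild-type replicate 1, Perp-null replicate 2 or Perp-null replicate 3 they were 0 and 1, where the smallest adjusted p after Perp was 0.0541, 0.0857 and 0.0823. Each fit without a sample had 3 residual degrees of freedom. This includes those without wild-type replicate 2 (2049 and 3109) and without Perp-null replicate 1 (2072 and 2967), which kept their calls. The 5 matched arrays scaled to the 75th percentile gave 36 higher and 6947 lower, so that 0.5% of calls were higher against 39.9%, and the median of all genes moved to -0.30. The same arrays with normexp and quantile normalisation gave 0 and 1 (7593 at an unadjusted p under 0.05), the slide block 0 and 1, and brighter genes only 0 and 1. The cause of these differences was not tested apart from the tests of background among the other observations. Signal over background may bear on most calls, as 93.3% have a mean log2 under 9, against 13152 of all 26677 tested genes.

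Whether the replicate numbers pair the samples depends on the genes used. The rule asked for a correlation over 0.1 in every pair, but no set of genes was fixed for it in advance, and the correlations were seen together with the calls. Deviations from the group means correlated at 0.407, 0.393 and -0.025 for numbers 1, 2 and 3 over all tested genes, so 1 pair lies under 0.1. Over genes of mean log2 of at least 10 they correlated at 0.824, 0.648 and 0.508, and every sample correlated best with its own number, which is a hint from the data and not from the design. With the replicate block limma called 0 genes higher and 0 lower (10144 at an unadjusted p under 0.05), and Perp, still at -9.31, had an adjusted p of 0.0799 with 2 residual degrees of freedom. With the replicate block on brighter genes only, 0 were higher and 1, Perp, lower (2388 at an unadjusted p under 0.05), and 4 lists passed in camera at the preset correlation. Of these the enamel list, at a median of -0.13, had 14 of 19 members lower (adjusted p = 0.0122), cell cycle at 0.15 had 33 of 38 higher (adjusted p = 0.0122), cartilage at -0.28 had 7 of 8 lower (adjusted p = 0.0122) and skeletal muscle at -0.31 had 11 of 14 lower (adjusted p = 0.0241). With an estimated correlation the adjusted p of each of the 4 was 0.768.

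The desmosome list failed to pass in all 21 alternatives, with medians from -0.17 to 0.097. The enamel list failed to pass in 19 of 21, with medians from -0.28 to 0.15. The highest of these, 0.15, came from the 5 matched arrays scaled to the 75th percentile, where the list passed (adjusted p = 0.0106), and the other pass is the replicate block on brighter genes. Lists past the threshold numbered 0 in the main setting, 9, 9 and 10 with the scanner files as stored (75th percentile, normexp, quantile), 10 with the 5 matched arrays at the 75th percentile, 0 to 1 when a sample was left out, and 1 each with the filter on all 6 arrays, array weights, the matched arrays with normexp and quantile normalisation, the slide block and brighter genes only. The 1 list was skeletal muscle, lower, with the filter on all 6 arrays (-0.68), the matched arrays with normexp and quantile normalisation (-0.67), the slide block (-0.91), brighter genes only (-0.31) and without Perp-null replicate 2 (-0.83). It was cell cycle, higher, with array weights (0.50) and without Perp-null replicate 1 (0.57), and red blood cells, higher, without wild-type replicate 2 (0.92).

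Values that changed sign follow, where a sign change counts only if the main or the alternative value was called (34 uncalled values that changed sign are not listed). With the scanner files as stored and 75th percentile scaling 17 named genes reversed: Axin2 -0.61, Cd163 -1.11, Cd3e -0.11, Cdc25a -0.16, Chil3 -0.82, Cldn4 0.026, Des 0.0044, Ebf2 -0.35, Fosb -0.044, Fpr2 -1.26, Klhl4 -1.62, Lcn2 -0.29, Pmaip1 -0.065, Pou3f1 -0.071, Serpini1 -0.73, Tcap 0.34 and Tgm3 -0.25. List medians that reversed there were dental mesenchyme -0.41, endothelium -0.91, leukocytes and osteoclasts -0.48 and skeletal muscle 0.34. With normexp 26 genes reversed: Axin2 -0.87, Cd163 -1.08, Cd3e -0.66, Cdc25a -0.43, Chil3 -0.89, Cyp2g1 -0.65, Des 0.013, Dsg3 -0.17, Ebf2 -0.86, Egr2 -0.0088, Fosb -0.65, Fpr2 -1.19, Gtse1 -0.17, Hbb-y -0.11, Klhl4 -1.37, Lcn2 -0.64, Mc4r -0.38, Ovgp1 -0.14, Pmaip1 -0.61, Pou3f1 -0.63, Serpini1 -0.86, Sox2 -0.56, Sprr1a -0.072, Tbc1d24 -0.50, Tcap 0.28 and Tgm3 -0.67, with the lists dental mesenchyme -0.41, endothelium -0.78, leukocytes and osteoclasts -0.52 and skeletal muscle 0.074. With quantile normalisation 21 genes reversed: Axin2 -0.77, Cd163 -0.995, Cdc25a -0.48, Chil3 -0.92, Cldn16 0.11, Cldn4 0.15, Des 0.26, Dlx6 0.042, Ebf2 -0.30, Fpr2 -1.34, Gtse1 -0.14, Irf7 0.030, Klhl4 -1.87, Krt4 0.052, Lcn2 -0.33, Pmaip1 -0.23, Pou3f1 -0.17, Serpini1 -0.93, Tbc1d24 -0.047, Tcap 0.46 and Tgm3 -0.14, with the lists cornified epithelium 0.23, dental mesenchyme -0.38, endothelium -0.91, leukocytes and osteoclasts -0.41 and skeletal muscle 0.42. The odontoblast and dentin list turned only in its camera direction, from up to down, in these 3 settings: its median was -0.59, -0.50 and -0.53, against -0.053 in the main setting. In these 3 settings 4 of the files have the rank order of another sample's column. On the 5 matched arrays scaled to the 75th percentile 10 genes reversed: Cd163 -0.86, Cd3e -1.40, Dsg3 -0.83, Egr2 -0.27, Fosb -1.66, Lcn2 -0.60, Pmaip1 -0.42, Sox2 -0.094, Sprr1a -0.51 and Tgm3 -1.63. The hemidesmosome list, at 0.079, reversed there too. The cell cycle list passed there with a median of -0.061, against 0.15 in the main setting, while its camera direction was up in both. The cause was not tested.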

Other observations

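The 2 tests of other groupings of the samples, the test of the genes beside Perp and the test of background in the enamel list were chosen before their results were seen, and the other tests after. Among the replicates, replicate 1 of each genotype stood apart in enamel and proliferation genes. Wild-type replicate 1 had a median of 0.31 over the 22 enamel genes and -0.81 over the 38 cell cycle genes, relative to each gene's mean over the 6 samples, and Perp-null replicate 1 had 0.34 and -0.78. The other 4 samples lay between -0.34 and 0.028 for enamel and between 0.27 and 0.62 for cell cycle. Odontoblast and dentin genes had medians of 0.31 and 0.37 in the replicates numbered 1, of 0.40 and -0.022 in those numbered 2 and of -0.66 and -0.35 in those numbered 3.

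This pattern was weighed first. Between replicates 1 and 2 the enamel list differed by a median of 0.40 in wild-type and 0.66 in Perp-null germs (18 and 19 of 22 genes higher in replicate 1), and the cell cycle list by -1.08 and -1.36 (0 of 38 genes higher in replicate 1 in either genotype). A background signal that differs between arrays would act on dim genes, but without members of mean log2 under 10 the enamel difference was 0.50 in wild-type and 0.96 in Perp-null germs, which argues against it. A germ stage that differs between replicate numbers stays open. The enamel and cell cycle lists prompted that explanation and so cannot test it. The odontoblast and dentin list, which it would move with enamel, differed by 0.19 in wild-type and 0.31 in Perp-null germs (13 and 15 of 22 genes higher in replicate 1, exact binomial sign test p = 0.523 and 0.134), too little to decide. The labels give no litter or dissection for a number, so shared litters, shared handling and chance remain open too, and no effect of genotype was tested by this.

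The scanner files and the value table attach arrays to samples differently. For 4 columns the rank order equals that of a scanner file stored under another sample, which is consistent with scanner files stored under the wrong samples. A wrong genotype for value table columns is argued against by Perp, whose lowest wild-type value exceeds its highest Perp-null value by 8.71 on the log2 scale. An exchange of columns within a genotype, which would leave the group means as they are, stays open. No biological explanation applies, as the design offers none for a mismatch of files.

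The genes called between genotypes were mostly dim, and the background signal of the matched arrays differed with genotype and with position on the slide. Genes of olfactory, vomeronasal and trace amine receptors and defensins, for which no role in a molar germ is known here, were called lower in 40.2% of 328 cases, against 21.8% of other genes matched on brightness (higher in 6.4% against 11%). Their median difference was -0.61, and -4.31 and -0.45 on the 5 matched arrays with 75th percentile scaling or with normexp and quantile normalisation. Among probes well above background on all 6 arrays 55 of the 328 remained, with a median of -0.0067, 50.9% lower and 5 called lower, but that filter also removes genes that fell to background. The main filter of 3 arrays could admit a gene through the matched wild-type arrays alone, which favours genes lower. Matching on brightness may not remove this. The array that matches no column has Perp bright and a negative control median of 65.5, between the matched genotypes. Quantile normalisation was examined with the median signal of the 5 matched arrays, scaled to the 75th percentile without that step. There 100% of the 3634 genes called lower other than Perp were lower, with a median of -2.81. The same arrays gave the calls, and this scaling lowered most genes called higher too, so a lower value was likely in advance. The test shows only that these genes stayed lower without quantile normalisation, and does not decide whether it is their whole cause. For the 2413 genes called higher quantile normalisation stays open and may be a cause, since 22% were higher there. Scaling alone left the median of all genes at -0.38, and the genes called higher at -0.39. With background-subtracted signal 47.2% of them were higher. With that signal 100% of the 3634 genes called lower stayed lower, with a median of -4.35, so subtracting background did not remove these decreases. Background or another difference between arrays may account for many of these calls, and these tests do not decide between them. An effect of the loss of Perp on dim genes, on the largest increases or on the largest decreases after Perp cannot be told apart from such differences between arrays. The same holds for list genes with the sample order of the largest decreases. Background, position on the slide and genotype are confounded on the matched arrays. In a separate fit of the 13525 genes of mean log2 of at least 9, 0 genes other than Perp were called, while the main fit called 407 genes at that level, Perp included.

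Of the 10 splits of the 6 columns into 3 and 3, 1, the real one, gave as many genes higher (2413, highest other 3) and 1, again the real one, as many lower (3635, highest other 3). With 10 splits the share cannot fall under 0.05.

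A hypothesis that the mutant carries a segment of another strain's chromosome around Perp was tested on the 40 nearest genes with a mean log2 of at least 9, of which 2 had an unadjusted p under 0.05, against 767 of 10258 others. The one-sided Fisher exact p was 0.811, so no excess was found. Of the 40, 0 were called, which says little, as the main fit called only 407 of the 13525 features at that level.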
